A study of Homo sapiens with 6 samples.

How the data were processed

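RNA of A549 cells with a scrambled shRNA or an shRNA against C19orf12 was sequenced as polyadenylated RNA, with 3 libraries in each of 2 groups. The deposited files give, per gene, RSEM expected counts, which are estimated counts and need not be whole numbers, as deposited by the authors. The same files hold FPKM values, per the file headers, scaled by the authors for gene length and depth. They also hold a gene length, the mean transcript length in bases, per the file headers. Per the submitters' processing notes, BWA, Bowtie2 and RSEM were used with genome build hg19; which aligner served which step, and the versions, are not given in the sources used here. Each file held a single library, and totals of estimated counts ran from 10229890 to 10647587.

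Files listed no gene with a value of 0, so a gene missing from a file was treated as 0 counts in that library. In any file 20824 genes were listed, 16506 of them in all 6, and 4318 were missing from at least 1. Entrez gene IDs were matched to symbols with an annotation of GRCh38, which was used for names and chromosomes only, and no positions are reported. GC content was taken from GENCODE transcripts matched by RefSeq accession, and length from the deposited files. Of the IDs 20727 were matched and 97 were not, the latter with 0.15% of the counts. Where a count was 0 in a library, 3 counts, or 0.29 CPM at the most, are the limit that counting allows. Replicate numbers were taken from the labels, which do not say whether replicates came from separate cultures.

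Expected counts were rounded to whole numbers and analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 14812. Libraries were scaled by TMM, and glmQLFit and glmQLFTest compared knockdown with scramble, without covariates. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. Errors of log2 fold changes (SE) were obtained from the fold change and the square root of its F statistic, and errors of levels are SDs of 3 libraries. CPM values are scaled by TMM.

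Gene lists were tested with limma 3.58.1 on voom values by camera with a preset correlation of 0.01, 2-sided, with Benjamini-Hochberg adjustment over 46 lists with at least 5 tested members, of 51 lists fixed in all. Results with an estimated correlation and by fry stand beside them.

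The lists, the design, the rule for named genes and the alternatives not marked otherwise were fixed before the data were examined. Named are C19orf12, the 12 genes with the highest and the 12 with the lowest log2 fold change among called genes with a mean of at least 5 CPM, all 3 knockdown libraries on 1 side of all 3 scramble libraries and a protein-type symbol, up to 4 called members with the smallest p-values and up to 2 uncalled members of each list, and the measured 19q12 neighbours. Some genes that this rule takes are not reported here. Genes named outside this rule are marked as chosen after their values were seen.

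Alternatives were RLE size factors, upper-quartile scaling, no filter on low counts, a filter of at least 1 CPM in at least 3 libraries, the replicate number as a block, each library left out in turn, DESeq2 1.42.0, limma-voom, a minimum log2 fold change of 1 and glmTreat against 1.5-fold. Chosen after seeing the data were a correction for GC content and length by a spline with 5 degrees of freedom per library, on 14231 genes with a GC value, library quality weights by limma, list counts without scramble replicate 3 and the estimated correlation without that library.

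The procedure was tested on simulated data with 200 changed genes. With the spread of all 6 libraries it recovered 7.5% of genes changed 1.5-fold, 65.7% of those changed 2-fold and 100% of those changed 4-fold, with 8 false calls, and 0 calls when no gene was changed. With the spread of the libraries other than scramble replicate 3 it recovered 74.6%, 92.5% and 98.5%, with 14 false calls, and 2 calls when no gene was changed. Both simulations had 3 libraries in each group and independent spread. They carried no shift of scramble replicate 3 with GC content and no smaller scramble group, so they do not give the recovery in the real comparisons. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.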

Results

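Polyadenylated RNA was sequenced from A549 cells, a human lung adenocarcinoma line, that carried either a scrambled control shRNA or an shRNA against C19orf12, with 3 libraries in each group. C19orf12 encodes a membrane protein found in mitochondria and the endoplasmic reticulum, and mutations of the gene cause a form of neurodegeneration with brain iron accumulation. The total estimated count per library lay between 10229890 and 10647587, and 18286 to 18582 genes were listed per library. Libraries are named here by group and replicate number. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure the spread between these libraries.

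Scramble replicate 3 stood apart from the other libraries. Across genes, its log2 CPM (counts scaled to a common library total) correlated with those of scramble replicates 1 and 2 at 0.953 and 0.954. The correlation was 0.994 between scramble replicates 1 and 2, and 0.9655 to 0.9664 between these and the knockdown libraries. Scramble replicate 3 thus lay further from scramble replicates 1 and 2 than the knockdown libraries did. Genes are not independent replicates. The 100 most abundant genes of scramble replicate 3 held 22.5% of its counts, against 18.9% and 18.8% in scramble replicates 1 and 2 and 20.2% to 20.3% in the knockdown libraries. Transcripts low in GC were lower in it: in the tenth of genes with the lowest GC content the median difference from the mean of scramble replicates 1 and 2 was -1.03 on the log2 scale, and in the tenth with the highest GC content it was 0.51. Counts of changed genes are therefore also given without this library. This alternative was planned, but the member counts of gene lists without it were added after the data were seen. The estimated coefficient of variation between replicates was 18.9% with all 6 libraries and 3% without scramble replicate 3. Adjusted p-values without that library are measured against this small spread, which may not cover differences between separate cultures.

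**Figure D1:**
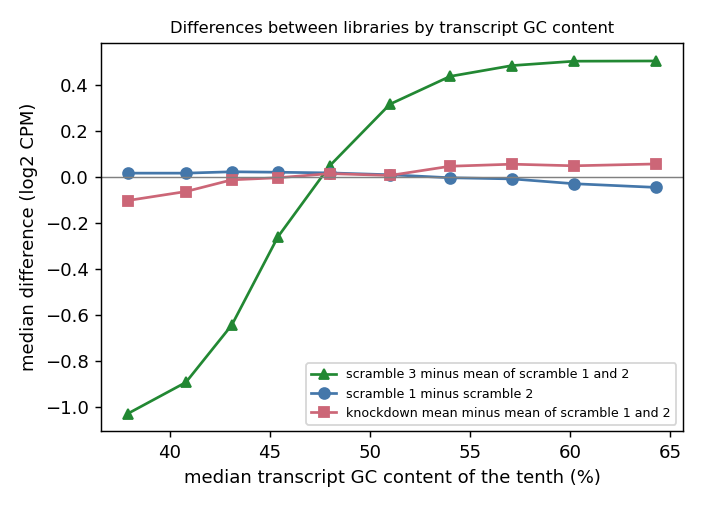
Median difference in log2 CPM between libraries (y axis) for 10 groups of genes of about equal size ordered by transcript GC content (x axis, percent). Scramble replicate 3 minus the mean of scramble replicates 1 and 2 runs from -1.03 to 0.51, while scramble replicate 1 minus replicate 2 and the knockdown mean minus the mean of scramble replicates 1 and 2 lie between -0.10 and 0.06.

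C19orf12, the targeted gene (Entrez gene 83636, chromosome 19), was lower in each knockdown library than in each scramble library. It measured 42.5, 41.1 and 63.3 CPM in scramble replicates 1, 2 and 3 and 24.2, 26.4 and 25.2 CPM in knockdown replicates 1, 2 and 3, with means of 49.0 ± 12.4 and 25.3 ± 1.08 CPM (SD, n = 3 each). The knockdown libraries held 51.6% of the scramble level, or 60.4% with scramble replicate 3 left out. The log2 fold change was -0.95 (SE 0.20, adjusted p = 0.015 by edgeR), and without scramble replicate 3 it was -0.73 (adjusted p = 3.17e-08). The call was lost without knockdown replicate 1 (-0.92, adjusted p = 0.0908), knockdown replicate 2 (-0.99, adjusted p = 0.0755) or knockdown replicate 3 (-0.95, adjusted p = 0.0879).

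**Figure D2:**
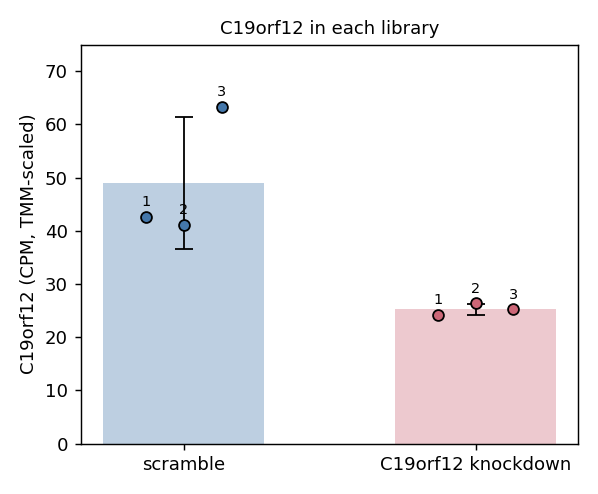
C19orf12 in TMM-scaled CPM (y axis) in the 3 scramble and the 3 knockdown libraries. Points are libraries, bars are means and error bars are SDs; the knockdown libraries lie between 24.2 and 26.4 CPM and the scramble libraries between 41.1 and 63.3 CPM.

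The comparison of knockdown with scramble cells asked which genes differ in expression when C19orf12 is lowered. Fibrinogen genes, the cell adhesion gene CEACAM6, the growth factor gene BMP2 and the receptor gene KIT were far higher in the knockdown libraries, while many targets of the stress transcription factor ATF4, neutrophil chemokine genes and the ferritin heavy chain gene were lower. Of 14812 genes tested, 1708 (11.5%) changed by edgeR's quasi-likelihood test, 873 higher and 835 lower. Among these, 528 rose and 382 fell at least 2-fold, and 94 rose and 1 fell at least 8-fold. The groups did not overlap for 5485 genes (37%, where chance gives 10%). Without scramble replicate 3 the count was 7439 of 15029 genes tested, with 3857 higher and 3582 lower, and 1707 of the 1708 genes were among them. These calls were made against the 3% spread between the remaining replicates, so small differences passed. Without knockdown replicate 1, 2 or 3 the counts were 766, 742 and 729, with 472, 465 and 460 higher and 294, 277 and 269 lower, so the near balance of higher and lower genes was not kept there.

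The highest fold changes included the 3 chains of fibrinogen, the clotting protein that the liver secretes. FGA rose from 29.7 ± 4.09 to 783 ± 12.8 CPM, FGB from 14.6 ± 3.09 to 445 ± 22.3 CPM and FGG from 19.1 ± 3.68 to 595 ± 4.36 CPM (SD, n = 3 each), with log2 fold changes of 4.72, 4.93 and 4.96. CEACAM6 was the most abundant of the 12 highest genes in the knockdown libraries, rising from 60.8 ± 10.4 to 1895 ± 54.4 CPM (log2 fold change 4.96, SE 0.18). BMP2, a bone morphogenetic protein, rose from 1.92 to 78.9 CPM, TRIM31, a ubiquitin ligase, from 2.07 to 81.2 CPM, and the potassium channel gene KCNJ16 from 1.18 to 37.6 CPM. Under 1 CPM in the scramble libraries were S100A9, a calcium-binding protein of neutrophils (0.285 to 23 CPM), the RNA-binding protein CELF2 (0.125 to 10.5 CPM), the anoctamin ANO3 (0.374 to 21.6 CPM), the receptor tyrosine kinase KIT (0.28 to 15.3 CPM) and the polarity gene CRB1 (0.281 to 14.3 CPM). Adjusted p-values of the 12 genes by edgeR ran from 1.54e-06 for TRIM31 to 2.17e-05 for KIT. CEACAM6 in scramble replicate 3 was at 50.9 CPM, FGA at 33.8, FGB at 11 and FGG at 14.9 CPM. Without that library the log2 fold changes were 4.85, 4.82, 4.76 and 4.80. Counts of CEACAM6 are estimates that divide reads among closely related CEACAM genes.

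The lowest fold changes were smaller in size. DHRS2, a short-chain dehydrogenase, fell from 79.8 ± 20.9 to 10.4 ± 0.826 CPM (log2 fold change -2.94, SE 0.22), and UNC5B, a netrin receptor, from 97.6 ± 21.8 to 23.6 ± 1.42 CPM (-2.04, SE 0.20). The neutrophil chemokine CXCL8 fell from 18.9 to 4.62 CPM. The kinesin gene KIF1A (-2.75) and the calcium channel genes CACNG7 (-2.30) and CACNA1H (-2.07) fell. The remaining members were BEX2 (-2.25), TMEM59L (-2.24), the actin-binding protein ABLIM3 (-2.88), the protocadherin PCDH1 (-2.38), the peptidylarginine deiminase PADI3 (-2.03) and EYA2 (-1.98). Adjusted p-values of the 12 genes by edgeR ran from 6.76e-05 for DHRS2 to 0.00213 for EYA2. DHRS2 in scramble replicate 3 was at 104 and UNC5B at 123 CPM, and without it their log2 fold changes were -2.71 and -1.85.

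**Figure D3:**
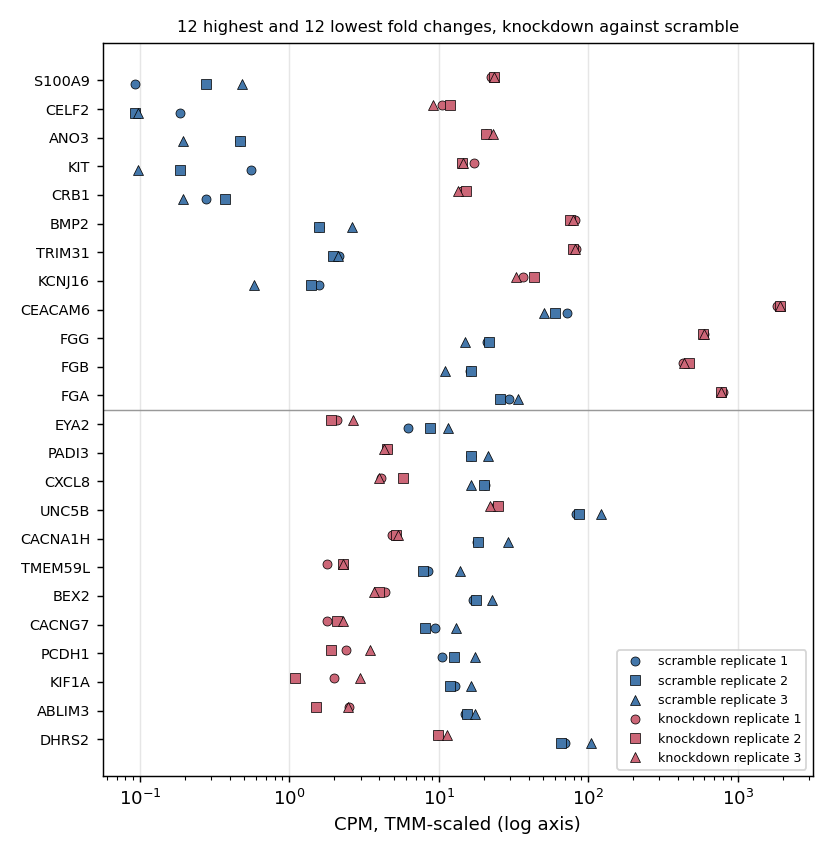
CPM on a log axis of the 12 genes with the highest and the 12 genes with the lowest log2 fold change, with a point per library. For each gene all 3 knockdown libraries lie on the same side of all 3 scramble libraries; CEACAM6 averages 1895 CPM in the knockdown libraries and DHRS2 10.4 CPM.

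Of 46 gene lists with at least 5 measured members, 17 were called by camera with a preset correlation of 0.01, 10 higher and 7 lower. With an estimated correlation 0 were called, where the adjusted p-values of the 17 ran from 0.236 to 0.837 and 5 of the 46 lists had an unadjusted p under 0.05. By fry, which tests whether the genes of a list move on balance in 1 direction, 11 of the 17 held; the lists of respiratory chain, mitochondrial ribosome, glycolysis, immediate early, mesenchymal and NRF2 target genes did not. Without scramble replicate 3, 15 of the 17 held by camera with the preset correlation. In that setting 7439 of 15029 genes tested were called. Counts of called members without that library are to be read against this share, and alone they do not mark a list. In 8 of the 46 lists, none of them among the 17, the median, the mean and the direction of the test differed in sign. Median shifts of scramble replicate 3 from the mean of scramble replicates 1 and 2 are given by list below. Over all genes with a GC value this shift was 0.32 in the tenth with a median GC content of 51%. It was 0.44 in the tenth at 54% and -0.64 in the tenth at 43.1%. The shift of a list need therefore not be particular to its genes.

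**Figure D4:**
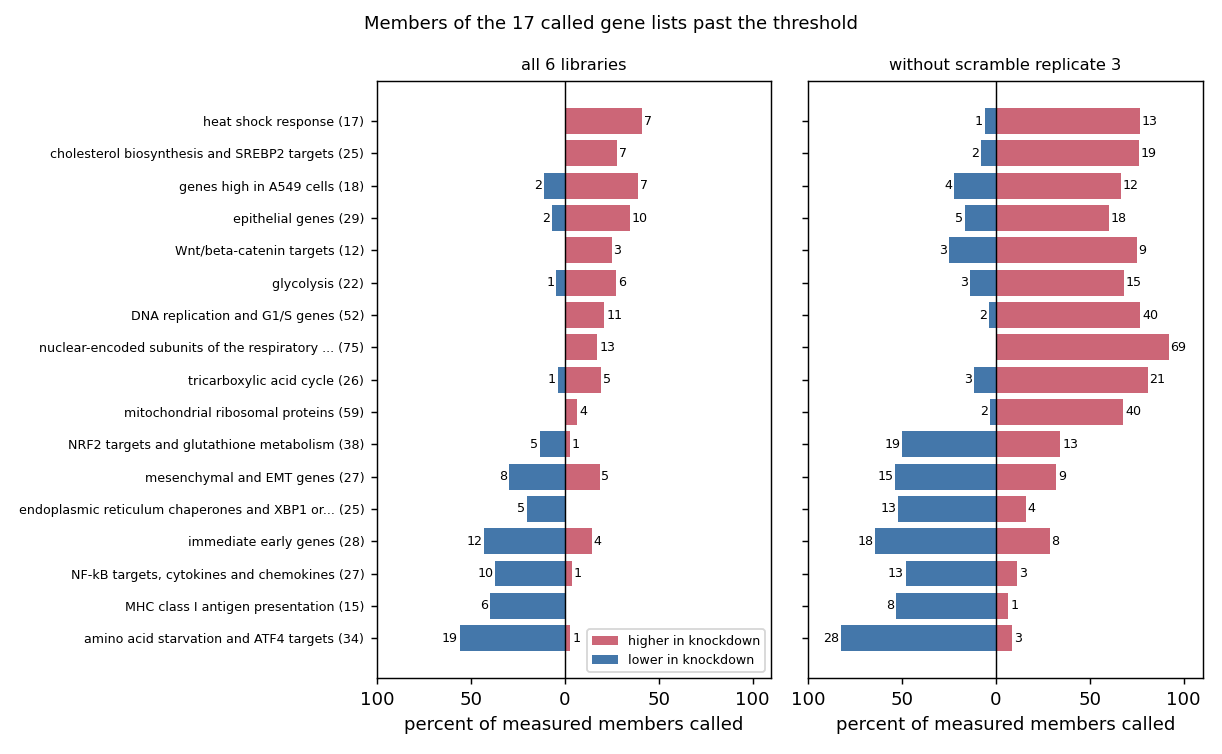
Percent of the measured members of each of the 17 called gene lists that were called higher or lower in the knockdown libraries, with all 6 libraries and without scramble replicate 3. With all 6 libraries 19 of 34 ATF4 targets fell and 13 of 75 respiratory chain genes rose, and without scramble replicate 3 the counts were 28 and 69.

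Amino acid starvation and ATF4 target genes were lower in the knockdown libraries. Of 34 measured, 19 fell and 1 rose, and adjusted over the list alone 24 fell and 2 rose (median log2 fold change -0.63, camera adjusted p = 2.12e-10, adjusted p = 0.407 with an estimated correlation and 0.0126 by fry). The stress-induced cytokine GDF15 fell from 249 ± 56.2 to 77.3 ± 2.9 CPM, the stress transcription factor DDIT3 from 110 ± 22.9 to 41 ± 2.1 CPM and CBS, which makes cystathionine from homocysteine, from 166 ± 38.3 to 61.5 ± 3.5 CPM. CTH, the enzyme after CBS in that pathway, was the member that rose, from 34.8 ± 0.944 to 79.5 ± 2.6 CPM. The amino acid transporter gene SLC7A5 (0.56, adjusted p = 0.059) and CEBPG (-0.71, adjusted p = 0.0626) did not pass the edgeR test with all 6 libraries but did without scramble replicate 3 (0.77 and -0.92, adjusted p = 5.58e-17 and 2.63e-14). Genes for endoplasmic reticulum chaperones and targets of XBP1 or ATF6 were also lower, with 5 of 25 falling and 0 rising, and 5 and 1 adjusted over the list alone (median log2 fold change -0.23, camera adjusted p = 0.0202, adjusted p = 0.407 with an estimated correlation and 0.00693 by fry). Among them the chaperone gene HSPA5 fell from 1976 ± 112 to 979 ± 8.29 CPM, and the stress sensor gene ERN1 (-1.44), HYOU1 (-1.09) and XBP1 (-0.86) fell. The median member lay 0.50 above the mean of scramble replicates 1 and 2 in scramble replicate 3 on the log2 scale in the ATF4 list and 0.24 above it in the chaperone list. Without that library 28 of the ATF4 genes fell and 3 rose, and 13 of the chaperone genes fell and 4 rose.

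The lists of respiratory chain and tricarboxylic acid cycle genes were called higher by camera with the preset correlation. Of 75 nuclear-encoded subunits of the respiratory chain and ATP synthase, 13 rose and 0 fell, with 16 and 0 adjusted over the list alone (median log2 fold change 0.35, camera adjusted p = 5.38e-08, adjusted p = 0.821 with an estimated correlation and 0.16 by fry). NDUFB3 rose from 28.1 ± 0.884 to 50.8 ± 1.83 CPM, SDHA, the succinate dehydrogenase flavoprotein, from 115 ± 26.2 to 232 ± 2.95 CPM, UQCRB from 145 ± 9.85 to 241 ± 9.11 CPM and the ATP synthase gene ATP5MC3 from 146 ± 33.6 to 296 ± 7.39 CPM. The tricarboxylic acid cycle list had 5 of 26 genes higher and 1 lower, and 9 and 1 adjusted over the list alone (median log2 fold change 0.40, camera adjusted p = 0.00142, adjusted p = 0.612 with an estimated correlation and 0.0469 by fry), among them IDH3A (0.83), OGDH (0.83) and PC (0.83). Here the median member lay 0.52 above the mean of scramble replicates 1 and 2 in scramble replicate 3 in the first of these lists and 0.42 in the cycle list. Without that library 69 respiratory chain genes rose and 0 fell, and 21 cycle genes rose and 3 fell.

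Glycolysis and mitochondrial ribosome genes were higher by weaker calls. Of 22 glycolysis genes 6 rose and 1 fell, with 8 and 2 adjusted over the list alone (median log2 fold change 0.24, camera adjusted p = 0.0246, adjusted p = 0.821 with an estimated correlation and 0.136 by fry). The lactate dehydrogenase genes LDHA (0.97) and LDHB (0.85) and the lactate exporter gene SLC16A3 (1.49) rose, while the hexokinase gene HK2 fell (-1.38). Of 59 mitochondrial ribosomal protein genes 4 rose, MRPS25, MRPS14, MRPS22 and MRPS28, and 0 fell (median log2 fold change 0.13, camera adjusted p = 0.0234, adjusted p = 0.837 with an estimated correlation and 0.29 by fry). Adjusted over the list alone 0 passed by edgeR, with 13 at an unadjusted p under 0.05, and over all genes DESeq2 called 6 and limma-voom 4. The glycolysis call was lost without scramble replicate 1 (adjusted p = 0.14) or scramble replicate 2 (0.146), and so was the mitochondrial ribosome call (0.331 and 0.336). In scramble replicate 3 the median member lay 0.53 and 0.51 above the mean of scramble replicates 1 and 2 in these lists. Without that library 15 glycolysis genes rose and 3 fell, and 40 mitochondrial ribosome genes rose and 2 fell.

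Genes of DNA replication, cholesterol synthesis and the heat shock response were higher. Of 52 DNA replication and G1/S genes 11 rose and 0 fell, with 12 and 0 adjusted over the list alone (median log2 fold change 0.43, camera adjusted p = 1.50e-06, adjusted p = 0.285 with an estimated correlation and 0.00187 by fry). PCNA, the sliding clamp of DNA polymerase, rose from 221 ± 10.4 to 436 ± 15.1 CPM, and the helicase genes MCM6 (1.11) and MCM4 (0.90) rose. Of 25 genes of cholesterol biosynthesis and SREBP2 targets 7 rose and 0 fell, with 12 and 1 adjusted over the list alone (median log2 fold change 0.55, camera adjusted p = 1.41e-05, adjusted p = 0.297 with an estimated correlation and 0.00187 by fry). INSIG1, which retains the SREBP precursors in the endoplasmic reticulum, rose from 13.3 ± 0.785 to 34.5 ± 1.44 CPM, and ACAT2 (0.73) rose. Of 17 heat shock genes 7 rose and 0 fell, with 10 and 1 adjusted over the list alone (median log2 fold change 0.77, camera adjusted p = 0.000101, adjusted p = 0.236 with an estimated correlation and 0.00113 by fry). HSP90AA1 rose from 407 ± 137 to 1220 ± 60.6 CPM, HSPA8 from 608 ± 111 to 1338 ± 13.9 CPM, and HSPA1B (1.15) and HSPE1 (0.94) rose; HSPA1B has a near-identical copy, so its count is uncertain. The median member lay 0.36, 0.44 and 0.09 above the mean of scramble replicates 1 and 2 in scramble replicate 3 in the replication, cholesterol and heat shock lists. Without that library 40, 19 and 13 of their genes rose and 2, 2 and 1 fell.

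Epithelial genes were on balance higher. So was the list of genes high in A549 cells, in which the fibrinogen genes had the largest changes. Of 29 epithelial genes 10 rose and 2 fell, with 12 and 3 adjusted over the list alone (median log2 fold change 0.37, camera adjusted p = 0.00028, adjusted p = 0.236 with an estimated correlation and 0.000297 by fry). Besides CEACAM6, the related gene CEACAM5 rose from 5.46 ± 0.799 to 95.8 ± 1.66 CPM, the keratin gene KRT8 from 1331 ± 309 to 4615 ± 49.4 CPM and the polarity gene CRB3 from 1.1 ± 0.231 to 6.21 ± 1.09 CPM. EPCAM (1.06, adjusted p = 0.059) and AP1M2 (-0.68, adjusted p = 0.0708) did not pass the edgeR test with all 6 libraries but did without scramble replicate 3 (0.85 and -0.46, adjusted p = 0.0398 and 0.00792). Of 18 genes high in A549 cells 7 rose and 2 fell, with 10 and 4 adjusted over the list alone (median log2 fold change 0.61, camera adjusted p = 0.000193, adjusted p = 0.285 with an estimated correlation and 0.000297 by fry), and the fibrinogen genes and KRT8 are members of this list. Here the median member lay 0.24 and 0.27 above the mean of scramble replicates 1 and 2 in scramble replicate 3 in the epithelial and A549 lists. Without that library 18 of 30 epithelial genes rose and 5 fell, and 12 A549 genes rose and 4 fell. Of the 15 A549 genes other than fibrinogen, 4 rose and 2 fell with all 6 libraries. Without scramble replicate 3, 9 of these 15 rose and 4 fell.

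Mesenchymal genes were on balance lower and Wnt targets higher, by calls that did not hold in each setting. Of 27 mesenchymal genes 5 rose and 8 fell, with 5 and 14 adjusted over the list alone (median log2 fold change -0.48, camera adjusted p = 0.0234, adjusted p = 0.619 with an estimated correlation and 0.0654 by fry). The fibronectin gene FN1 fell from 904 ± 17.5 to 424 ± 10.2 CPM, COL6A2 (-1.46) fell, THBS1 rose (1.23), and the vimentin gene VIM was at -0.48 (adjusted p = 0.0965 by edgeR, and -0.30, adjusted p = 2.52e-08, without scramble replicate 3). Of 12 Wnt target genes 3 rose and 0 fell, with 8 and 3 adjusted over the list alone (median log2 fold change 0.43, camera adjusted p = 0.0372, adjusted p = 0.407 with an estimated correlation and 0.00187 by fry). Those that rose were TNFRSF19 (2.07), AXIN2 (1.23) and TCF7 (0.66). The mesenchymal call was lost without scramble replicate 3 (adjusted p = 0.0762). The Wnt call was lost without scramble replicate 1 (0.101), without scramble replicate 2 (0.0735) and with no filter on low counts (0.242). In scramble replicate 3 the median member lay 0.49 and 0.11 above the mean of scramble replicates 1 and 2 in these lists. Without that library 9 of 28 mesenchymal genes rose and 15 fell, and 9 Wnt targets rose and 3 fell.

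Chemokine, immediate early and antigen presentation genes were lower. Of 27 NF-kB target, cytokine and chemokine genes 10 fell and 1 rose, with 13 and 2 adjusted over the list alone (median log2 fold change -0.46, camera adjusted p = 0.000549, adjusted p = 0.407 with an estimated correlation and 0.00631 by fry). The neutrophil chemokine gene CXCL2 fell from 35.4 ± 3.81 to 10.8 ± 0.493 CPM, CXCL3 (-1.32) and CXCL8 (-2.03) fell, and C3, the central complement protein, rose from 9.81 ± 3.17 to 93.2 ± 2.24 CPM. Of 28 immediate early genes 12 fell and 4 rose, with 15 and 5 adjusted over the list alone (median log2 fold change -0.50, camera adjusted p = 0.00497, adjusted p = 0.821 with an estimated correlation and 0.104 by fry). JUN (-1.22) and the feedback inhibitors of growth factor signalling DUSP6 (-1.14) and SPRY2 (-1.22) fell, while the nuclear receptor gene NR4A1 rose from 59.9 ± 8.59 to 202 ± 2.88 CPM. Of 15 MHC class I genes 6 fell and 0 rose, with 6 and 0 adjusted over the list alone (median log2 fold change -0.46, camera adjusted p = 0.00586, adjusted p = 0.612 with an estimated correlation and 0.047 by fry). HLA-B fell from 68.5 ± 20.1 to 35.4 ± 0.522 CPM, and HLA-F (-0.69) and the immunoproteasome gene PSMB8 (-1.18) fell; HLA genes share sequence, so their counts are uncertain. The median member lay 0.36, 0.46 and 0.42 above the mean of scramble replicates 1 and 2 in scramble replicate 3 in these 3 lists. Without that library 13, 18 and 8 of their genes fell and 3, 8 and 1 rose.

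NRF2 target and glutathione genes were lower by a call near the threshold. Of 38 measured, 5 fell and 1 rose, with 6 and 2 adjusted over the list alone (median log2 fold change -0.17, camera adjusted p = 0.0498, adjusted p = 0.821 with an estimated correlation and 0.205 by fry). The transporter gene ABCC3 (-0.87) and TRIM16L (-0.83) fell, and the glutathione transferase gene MGST1 rose (0.64). The call was lost without scramble replicate 3 (adjusted p = 0.0553), knockdown replicate 2 (0.0519) or knockdown replicate 3 (0.0755), with a stricter filter (0.0509) and with a GC and length correction (0.0841). Here the median member lay 0.50 above the mean of scramble replicates 1 and 2 in scramble replicate 3, and without that library 19 genes fell and 13 rose.

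Iron genes moved in both directions. Of 28 measured genes of iron uptake, storage and export 1 rose and 3 fell, with 3 and 3 adjusted over the list alone, and the list was not called (camera adjusted p = 0.786). The transferrin receptor gene TFRC rose from 81.7 ± 37.6 to 245 ± 4.51 CPM (log2 fold change 1.59, SE 0.33, adjusted p = 0.0136 by edgeR). The ferritin heavy chain gene FTH1 fell from 5370 ± 1258 to 2801 ± 40.1 CPM (-0.94, SE 0.17, adjusted p = 0.00714 by edgeR), and STEAP1 (-0.69) and the mitochondrial iron importer gene SLC25A37 (-0.52) fell. Scramble replicate 3 held 38.2 CPM of TFRC and 6822 CPM of FTH1, and without it the log2 fold changes were 1.25 and -0.73. In that library the median member of the list lay 0.24 above the mean of scramble replicates 1 and 2, and without it 10 genes rose and 9 fell. FTH1 has processed pseudogenes, so its count is uncertain. Of 12 other genes of neurodegeneration with brain iron accumulation 0 were called by edgeR, DESeq2 or limma-voom, and 2 had an unadjusted p under 0.05 by edgeR. Their median in scramble replicate 3 lay 0.46 above the mean of scramble replicates 1 and 2, and without that library 2 rose and 6 fell.

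Among lists without a call, several held genes with large changes. Of 34 interferon-stimulated genes 6 rose and 4 fell, with OAS1 rising from 20 ± 4.84 to 57.4 ± 0.262 CPM and SAMD9 from 1.15 ± 0.578 to 9.14 ± 1.02 CPM. Of 35 p53 targets 4 rose and 6 fell; KITLG, the ligand of KIT, rose from 4.99 ± 2.03 to 48.1 ± 3.06 CPM and GADD45A fell from 103 ± 13.7 to 34.1 ± 1.7 CPM. Of 31 BCL2 family and caspase genes CASP9 alone rose, from 16.2 ± 3.84 to 90 ± 2.56 CPM, and BBC3 alone fell (-1.14). Of 25 HIF1 targets 1 rose and 6 fell, HILPDA (-1.28) and ADM (-0.85) among them, and of 22 YAP/TAZ-TEAD targets 3 rose and 6 fell, AXL (-1.21) and AJUBA (-1.17) among them. Among integrins and laminins, 5 of 24 rose and 1 fell; ITGB4 rose from 364 ± 84.2 to 1042 ± 10.8 CPM and ITGA10 fell (-2.32). Of 58 genes of G2 and mitosis KIF20A rose (0.76) and UBE2C (-0.87) and CDC25B (-0.61) fell. Camera adjusted p-values of these 7 lists were 0.706, 0.42, 0.932, 0.188, 0.215, 0.628 and 0.932 in the order given, but fry called the HIF1 list (adjusted p = 0.00631, against 0.612 by camera with an estimated correlation). The camera direction of the interferon and the integrin and laminin lists turned from up to down without scramble replicate 3. The median member of scramble replicate 3 differed from the mean of scramble replicates 1 and 2 by 0.09, 0.32, 0.12, 0.26, -0.07, -0.23 and -0.65 on the log2 scale. Adjusted over the list alone the counts higher and lower were 8 and 5, 5 and 6, 1 and 1, 1 and 6, 3 and 6, 6 and 4, and 1 and 1. Without scramble replicate 3 they were 9 and 12, 10 and 15, 9 and 9, 6 and 12, 7 and 12, 7 and 11, and 12 and 20. Of all genes tested in that setting, 7439 of 15029 were called.

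Lipid, protease and zinc genes changed singly. Of 31 genes of lipid droplets and phospholipids 1 rose, PLIN3 (1.47), and 4 fell, PLIN2 (-1.15) among them. The fatty acid desaturase gene SCD rose from 1131 ± 159 to 2473 ± 95.2 CPM and ACSL1 fell (-0.67), of 16 genes of fatty acid synthesis, and of 21 genes of fatty acid oxidation 2 rose, DECR1 (0.58) among them, and 0 fell. Of 36 autophagy genes PIK3C3 rose and 3 fell, MAP1LC3B from 133 ± 3.83 to 72.7 ± 0.551 CPM. Of 19 protease and inhibitor genes 3 rose and 3 fell; PLAU, the urokinase gene, rose from 104 ± 25 to 322 ± 9.07 CPM. The zinc exporter gene SLC30A1 rose (1.48) and the metallothionein genes MT2A (-1.11) and MT1X (-1.04) fell, of 6 measured. Of 14 Notch pathway genes NOTCH3 (0.69) and HES4 (0.94) rose and NOTCH1 fell (-0.65); of 18 ferroptosis genes 2 rose and 3 fell, SAT1 (-1.11) and CHAC1 (-1.04) among them; of 13 small RNA processing genes DROSHA rose (0.74) and TNRC6C fell (-0.59). These 9 lists were not called (camera adjusted p = 0.0804, 0.762, 0.877, 0.608, 0.877, 0.858, 0.877, 0.677 and 0.863 in the order given), but fry called those of fatty acid synthesis and proteases (adjusted p = 0.0153 and 0.0333, against 0.902 and 0.927 by camera with an estimated correlation). Camera called the lipid droplet list without scramble replicate 2 (adjusted p = 0.0447) and with the GC and length correction (0.0482). With an estimated correlation the list was called neither with all 6 libraries (adjusted p = 0.831) nor without scramble replicate 3 (0.736), and this correlation was not run in the other settings. Adjusted over the list alone their counts higher and lower were 1 and 4, 3 and 2, 2 and 0, 1 and 3, 8 and 3, 2 and 2, 2 and 1, 3 and 3, and 1 and 1, and without scramble replicate 3 they were 6 and 9, 8 and 5, 8 and 5, 8 and 12, 9 and 7, 2 and 2, 5 and 5, 8 and 6, and 3 and 3. Scramble replicate 3 differed from the mean of scramble replicates 1 and 2 by medians of 0.45, -0.10, 0.47, 0.14, 0.21, -0.53, 0.40, 0.41 and -0.46 in these lists.

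Cytosolic ribosomal protein genes differed by little with all 6 libraries. Of 78 measured, 0 were called by edgeR, DESeq2 or limma-voom, and 4 had an unadjusted p under 0.05 by edgeR; RPL6 was at 0.35 and RPL7 at 0.31, and at 0.38 and 0.24 without scramble replicate 3 (adjusted p = 1.09e-09 and 5.43e-07). Their median in scramble replicate 3 lay 0.53 above the mean of scramble replicates 1 and 2. Without that library 71 rose and 2 fell, and the list was called (camera adjusted p = 2.14e-20), but not with an estimated correlation (adjusted p = 0.237). The proteasome, lysosome and haem synthesis lists were likewise called without scramble replicate 3 (adjusted p = 7.27e-06, 0.00749 and 0.0389) and not with all 6 libraries (0.0804, 0.54 and 0.54). These 3 calls were also lost with an estimated correlation without that library (adjusted p = 0.237, 0.239 and 0.237). With all 6 libraries 1, 3 and 1 of their 31, 42 and 8 genes rose and 0, 1 and 0 fell, and without that library 24, 22 and 6 rose and 3, 6 and 0 fell. Of 29 coat protein and vesicle traffic, 18 mitochondrial fusion and fission and 38 ribosome biogenesis and MYC target genes 0 were called by edgeR, with 4, 4 and 5 at an unadjusted p under 0.05; DESeq2 called 2, 0 and 1 and limma-voom 0 of each, and without scramble replicate 3 edgeR called 7 higher and 5 lower, 6 higher and 4 lower and 18 higher and 7 lower. Camera adjusted p-values of these lists were 0.932, 0.877 and 0.762, and their medians in scramble replicate 3 differed by -0.02, 0.04 and 0.52 from the mean of scramble replicates 1 and 2.

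Of the 7 measured genes of the 19q12 neighbourhood, C19orf12 alone passed the edgeR test over all genes with all 6 libraries. The others were at log2 fold changes of 0.45 (CCNE1), 0.44 (UQCRFS1), 0.30 (POP4), 0.22 (URI1), 0.16 (PLEKHF1) and -0.91 (TSHZ3, adjusted p = 0.0546 by edgeR). Adjusted over the list alone 0 rose and 2 fell, C19orf12 and TSHZ3. Their median in scramble replicate 3 lay 0.45 above the mean of scramble replicates 1 and 2, and without it 3 rose and 2 fell.

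Markers of other cell types did not pass as lists. Among 8 alveolar type 2 markers 2 rose and 4 fell (camera adjusted p = 0.169); LPCAT1 rose from 70.6 ± 13.1 to 253 ± 6.22 CPM, and LAMP3 (-1.51), FOXA2 (-1.14) and ETV5 (-0.97) fell. Of 11 neural markers SNAP25 (1.11) and NEFL (1.32) rose and RBFOX3 (-1.32) and SYT1 (-1.50) fell, and of 8 genes high in the kidney line HEK293 NEFL alone rose (camera adjusted p = 0.877 and 0.706). Only 2 fibroblast, 4 haematopoietic and 1 endothelial markers passed the filter on low counts, too few for a list test, and among them COL1A1 fell (-0.75). The median in scramble replicate 3 lay 0.45, 0.08 and 0.44 above the mean of scramble replicates 1 and 2 in the alveolar, neural and kidney lists, and without it 2, 5 and 2 genes rose and 4, 4 and 2 fell. Among the tested genes were 0 of the 36 replication-dependent histone genes, whose transcripts carry no poly(A) tail, and 0 of the 13 mitochondrially encoded genes, under the symbols used here.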

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

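Lengths of the transcripts were outside the comparisons described so far, and the length test and the genes named in it were chosen after the data were seen. The mean transcript length of a gene in a library depends on which of its transcripts are present. Tested were 6375 genes with a mean of at least 5 CPM, a length in all 6 libraries and lengths that spanned more than 1 base. By limma on log2 lengths, 6 of these differed between the groups, 1 longer and 5 shorter in the knockdown libraries. Of the 6375 genes, 497 had an unadjusted p under 0.05 by limma. The highest count among the other 9 splits of the 6 libraries was 1, and without scramble replicate 3 the count was 8. SYTL2 went from 3750 ± 22 to 2855 ± 29 bases (SD, n = 3 each, log2 difference -0.39, limma adjusted p = 0.00137), CEACAM5 from 3533 ± 15 to 3101 ± 20 bases (-0.19, adjusted p = 0.00327) and SYNCRIP from 4991 ± 21 to 4480 ± 33 bases (-0.16, adjusted p = 0.00828). HAS3 went from 2068 ± 29 to 1672 ± 23 bases (-0.31, adjusted p = 0.011), SAT1 from 1161 ± 1 to 1141 ± 2 bases (-0.03, adjusted p = 0.0221) and, in the other direction, SH3YL1 from 2337 ± 40 to 3009 ± 45 bases (0.36, adjusted p = 0.011). In each of the 6 genes all 3 knockdown libraries lay on the same side of all 3 scramble libraries. SAT1 was not among the 8 without scramble replicate 3 (adjusted p = 0.0907), and the other 5 were.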

How the results depend on the processing

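The GC and length correction, the library quality weights and the estimated correlation without scramble replicate 3 were tests chosen after seeing the data; the other settings were planned. No result with a call in either setting changed direction; 3 named genes and 13 lists without a call did. The count of changed genes, 1708 with all libraries, stayed within 1.5 times under RLE size factors (1763), upper-quartile scaling (1728), no filter (1725), the stricter filter (1712), DESeq2 (1889), limma-voom (1659) and the replicate block (1654). It was 4858 with the GC and length correction (2191 higher and 2667 lower) and 7585 with library quality weights, where scramble replicate 3 had a weight of 0.032; the cause was not tested. A minimum log2 fold change of 1 left 910 and glmTreat against 1.5-fold left 590, by their own construction. With 1 library left out it ran from 729 to 7439. Of the genes called with all libraries, 1655 were also called with the GC and length correction, 1622 by DESeq2, 1631 by limma-voom and 1478 with the block. C19orf12 was between -1.08 and -0.73 with 1 library left out, and with the replicate block it was -0.93. It lost its call without knockdown replicate 1, 2 or 3. There the log2 fold change was -0.92, -0.99 and -0.95, against -0.95 with all libraries, while its SE was 0.27 against 0.20. The call was thus lost mainly through a larger error, and what enlarged the error was not tested. The number of lists called was 14 to 19 with 1 library left out, 16 with the replicate block, 14 by fry, 0 with an estimated correlation and 0 with an estimated correlation without scramble replicate 3, where the lowest adjusted p was 0.0877 and 9 lists had an unadjusted p under 0.05. The call of mitochondrial ribosomal proteins was also lost with the replicate block (adjusted p = 0.0651). Of 149 other named genes with a call, 98, 92 and 93 were called without knockdown replicate 1, 2 and 3, 122 and 121 without scramble replicate 1 and 2, 149 without scramble replicate 3 and 133 with the block. Of the uncalled results that turned, 2 genes and 6 lists did so without scramble replicate 3. With 1 library left out the genes ran over -0.006 to 0.31 (SLC30A5), -0.029 to 0.35 (PLEKHF1) and -0.095 to 0.15 (PECAM1). SLC30A5 was at -0.007 with library quality weights, and PECAM1 was at -0.096 with these, -0.003 with upper-quartile scaling and -0.042 with the GC and length correction. The lists turned by the direction of the test, which their medians need not share. With 1 library left out the medians ran over -0.097 to 0.18 (fatty acid oxidation), -0.045 to 0.052 (G2 and mitosis), -0.03 to 0.25 (ribosomal proteins), -0.081 to 0.16 (interferon), -0.099 to -0.036 (apoptosis), -0.12 to 0.04 (proteases), -0.22 to 0.25 (integrins and laminins), -0.22 to -0.089 (Notch), 0.013 to 0.067 (vesicle traffic), 0.19 to 0.34 (19q12), -0.11 to 0.28 (small RNA processing) and -0.26 to -0.12 (HEK293). With an estimated correlation without scramble replicate 3 the medians were -0.081 (interferon), 0.04 (proteases), -0.22 (integrins and laminins), -0.089 (Notch), -0.11 (small RNA processing) and -0.12 (HEK293). With the replicate block they were 0.062 (G2 and mitosis) and 0.24 (19q12), and with no filter -0.068 (proteases), 0.33 (neural) and 0.045 (HEK293). By fry, which leaves medians as they are, G2 and mitosis (0.042), apoptosis (-0.097) and Notch (-0.19) turned. No pairing by replicate number was seen: residual correlations across genes of same-number libraries were -0.02, -0.02 and -0.02, within the range of all pairs from -0.05 to 0.06. The shift of scramble replicate 3 enters the residuals of all scramble libraries, so a small effect shared by same-number libraries could be hidden. Of simulated 1.5-fold changes 7.5% were recovered with the spread of all 6 libraries and 74.6% with the spread without scramble replicate 3. Both simulations used full groups without a GC-linked shift, unlike the real comparisons, and depth was not varied. Pseudocount alternatives were not run because counts were present.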

Other observations

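Tests chosen only after the result was seen were those of cells of another type and of a mislabelled library for scramble replicate 3, of that library as the source, of hepatic and intestinal cells, of another cell line and of a chromosome gain for the highest genes, and of that library for the ATF4 list. Several gene families outside the fixed lists held large changes; they and their genes were chosen after their values were seen. A test by transcripts with iron-responsive elements was dropped, because counts per gene do not separate transcripts with and without such an element. Of 8 measured mucin genes 4 rose and 0 fell: MUC16, the CA125 antigen, rose from 16.3 ± 5.63 to 408 ± 52.8 CPM, MUC5B, a secreted airway mucin, from 233 ± 46 to 963 ± 37.1 CPM, and MUC13 from 34.1 ± 7.8 to 169 ± 3.96 CPM (SD, n = 3 each), with MUC1 (0.93) as the smallest of the 4, while MUC5AC was at -0.54 (adjusted p = 0.107 by edgeR, and 1.13e-05 without scramble replicate 3). Of 5 CEACAM genes 3 rose, CEACAM7 from 6.53 ± 1.27 to 126 ± 3.88 CPM besides CEACAM5 and CEACAM6. Of 12 keratin genes 5 rose and 2 fell; KRT18, the partner of KRT8, rose from 2220 ± 528 to 5500 ± 78.9 CPM, and KRT7 was at -0.003 with all 6 libraries and at 0.21 without scramble replicate 3 (adjusted p = 0.995 and 1.75e-06). Of 13 imprinted genes 3 rose and 3 fell: H19 rose from 15.3 ± 0.852 to 180 ± 4.68 CPM, whereas its neighbour IGF2 fell from 7.97 ± 1.03 to 1.73 ± 0.313 CPM. Of 18 coagulation and complement genes 6 rose and 1 fell, and SERPINA3 was at -0.79 (adjusted p = 0.103). Leaving out scramble replicate 3 gave 4 higher and 1 lower mucin, 3 and 1 CEACAM, 6 and 4 keratin, 3 and 6 imprinted, and 8 and 3 coagulation and complement genes. Without scramble replicate 3 the edgeR adjusted p-values of MUC16, CEACAM7, KRT18, H19 and IGF2 were 1.79e-19, 1.63e-20, 3.53e-22, 4.07e-21 and 7.19e-08.

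Scramble replicate 3 stood apart from scramble replicates 1 and 2. Across genes its difference from them correlated with transcript GC content at r = 0.698, and with length at a partial r of -0.34 after GC, so that a bias of library preparation or degraded RNA may account for much of it. Against cells of another type, 0 marker genes of any list were above both limits, 5 CPM and 4-fold. Against a mislabelled knockdown library, its median position over the 200 genes most different between knockdown and scramble was 0.044, where 0 is scramble and 1 is knockdown. GC content and length accounted for 60.5% of the variance of the difference across genes, and what made the rest was not tested.

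The 12 genes with the highest fold change kept log2 fold changes of at least 4.65 without scramble replicate 3 and of at least 4.59 with a GC and length correction. These genes were chosen for the largest fold changes, and a bias of a single scramble library could not have removed changes of this size. The values therefore give no test of that library or of GC content as a source. Against hepatic or intestinal cells in the knockdown libraries, the highest of 5 abundant hepatocyte genes had 0.863 CPM and the highest of 5 intestinal genes 3.19 CPM, far below FGA and CEACAM6. That intestinal gene, VIL1, itself rose (log2 fold change 2.065, adjusted p = 0.00147 by edgeR). Outside the 5, the intestinal gene CDH17 was at 65.7 CPM in the knockdown and 73.2 CPM in the scramble libraries. Against a gain of a whole chromosome the highest median log2 fold change among the 8 chromosomes that hold the 12 genes was 0.061. On chromosome 4, which holds 4 of the 12 genes, the median was -0.058 with all 6 libraries and -0.201 without scramble replicate 3. A median over a chromosome cannot show a gain of a small region, which was not tested. Against another cell line in place of A549, the lowest log2 fold change of the 11 genes of the A549 list with at least 100 CPM in the scramble libraries was -0.66, or -0.61 without scramble replicate 3; this test replaced a first limit of 20% on the share of the 15 list genes other than fibrinogen that fell, which was 13.3% with all 6 libraries and 26.7% without that library. An effect of lower C19orf12, an effect of the shRNA on other transcripts and a difference between the cultures before the knockdown remain open and could not be tested, since no other shRNA against C19orf12 was analysed here.

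The ATF4 target list was lower in the knockdown libraries with a median log2 fold change of -0.63. By camera with an estimated correlation it was not called (adjusted p = 0.407, and 0.0877 without scramble replicate 3). Without scramble replicate 3 the median was -0.54, and with a GC and length correction it was -0.67, which argues against both as the whole source. Differences in medium or cell density between the cultures may also change these genes and were not tested.

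For the count of changed genes, the real split of the 6 libraries gave 1708 and the highest of the other splits gave 0 by edgeR, with at most 424 genes at an unadjusted p under 0.05 against 3763. DESeq2 and limma-voom were not run on the other splits. Only 1 of the 10 splits gave as many, and 10 splits are too few for a share under 0.05.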
